A study of Mus musculus with 43 samples.

How the data were processed

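The 43 libraries are RNA-seq of epididymal white adipose tissue of male mice in 5 groups. Per the labels, RNA was extracted with TRIzol, had an integrity number above 7, was selected for poly(A), made into strand-specific libraries with dUTP and read as 150 bp pairs on an Illumina instrument. The authors deposited read counts per gene, per the file headers, and these counts were used as deposited. The authors also deposited FPKM values per gene, per the file headers, and log2(FPKM + 1) and log2(FPKM + 0.1) of the authors' deposited values were used only for alternatives. The aligner and the counting program are not given in the sources used here. The ratio of deposited FPKM to count per library total and gene length was constant within each library and ranged from 0.776 to 1.15 between libraries, within 0.0795 of the inverse of the TMM factor. The labels name the mm10 genome, but of 38989 genes matched to a GRCm38 annotation on the same chromosome 1.50% had the same start or end, so coordinates are printed as the files give them.

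Groups and doses were taken from the labels, and group definitions, comparisons, gene lists, named-gene rule and alternatives were fixed before the data were examined, apart from the additions named below. HFD was compared with SD, each SZ-A dose with HFD, the doses with each other, and a linear trend was fitted over the 4 high-fat groups. Counts of 56748 genes were filtered with filterByExpr, which left 20218. Differences were tested with edgeR 4.0.16 (TMM factors, robust quasi-likelihood F test, all 43 libraries in 1 fit) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, over all tested genes of a comparison. The other tools were limma 3.58.1, DESeq2 1.42.0 and statmod 1.5.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Group levels are means of CPM normalised with the TMM factors. Log2 CPM values were normalised likewise, with a prior count of 2.

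For 46 gene lists with 956 symbols, 955 of them in the files, camera was run with a preset correlation of 0.01, and again with the correlation estimated per list, and fry was run as an alternative. A list was called at an adjusted p under 0.05 over the lists. The diet signature was defined with the odd-numbered HFD libraries against SD, and scored in the others as the mean standardised log2 CPM of genes higher minus that of genes lower, standardised on the SD and odd-numbered HFD libraries. Scores were compared with an exact permutation test, two-sided, over all splits of the libraries. For genes shared by 2 comparisons with a common HFD group, counts were set beside n1 × n2 / N, beside 100 draws of permuted residuals tested with limma, in which no group differed or the diet difference alone was kept, and beside counts with the HFD libraries split.

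Genes were named by rule. For HFD against SD and each dose against HFD these were the 10 largest fitted rises and falls, and for the trend and between doses the 5 largest. They had to be called, to carry a symbol other than that of a predicted model, to have a mean of at least 1 CPM in the higher group, and to have at least 80% of the libraries of each group on their own side of the other group's median. In every comparison the rule added Ucp1, Cidea, Ppargc1a, Prdm16, Dio2, Elovl3, Cox8b, Adrb3, Lep, Adipoq, Pparg, Mest, Sfrp5, Fasn, Scd1, Ccl2, Tnf, Adgre1, Itgax, Trem2 and Col1a1. From a list called by camera it added the 2 to 4 members with the smallest p in the list's direction. Of the genes taken by the rule, 4 are not reported here.

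Library sets and libraries with other tissue RNA were defined after the data were seen. The sets were divided at the largest gap in the log share of counts on small noncoding RNA genes, with 22 libraries below it (set 1) and 21 above (set 2). A private gene of a library had at least 10 CPM there and over 20 times the median of all libraries, with a floor of 0.05 CPM, and 100 private genes or more marked a library. Marker lists of ciliated, general, vas deferens, epididymal duct, squamous and sebaceous epithelium were added at the same time.

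Recovery was tested on simulated negative binomial counts with the spread, totals and group sizes of the data, in which 200 genes and 1 list were changed per comparison. Of the genes changed 1.5-fold, 2-fold and 4-fold, 13.4%, 38.8% and 69.7% were recovered for HFD against SD (19839 genes tested). For SZ-A 200, 400 and 600 against HFD these were 25.4%, 29.9% and 77.3% (19819 genes), 10.4%, 31.3% and 71.2% (19821 genes), and 22.4%, 40.3% and 65.2% (19860 genes). Other genes called were 3, 3, 0 and 4.

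The alternatives fixed before were DESeq2 size factors and upper-quartile factors in edgeR, the DESeq2 Wald test, limma voom with quality weights, limma-trend on log2 FPKM, no filter beyond 1 count, a stricter filter (1 CPM in 7 libraries), only the groups of a comparison, the replicate number as a block, no robust estimate, stricter thresholds, and each library left out in turn. Added after the data were seen were library set as a term, each set alone, no libraries with other tissue RNA, and combinations of these, and splits of the libraries within library sets.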

Results

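RNA-seq libraries of epididymal white adipose tissue, the visceral fat pad beside the epididymis, were compared across 5 groups of male mice. Per the labels, 7 libraries came from mice on a standard diet with 10% fat (SD group). Another 10 came from mice on a diet with 60% fat (HFD group). A further 9, 8 and 9 libraries came from mice on the high-fat diet that also received SZ-A, the alkaloids of the mulberry twig drug Ramulus Mori (Sangzhi), at 200, 400 and 600 mg/kg/day. The series title speaks of browning of white fat and of thermogenesis in brown fat. The 43 libraries address the white fat side of that question. Total counts per library, in units of 1e6, ranged from 32.7 to 44.3 with a median of 37.6, and group medians from 35.7 (SD) to 38.9 (HFD). Levels of genes are normalised CPM, counts per 1e6 of a library total multiplied by its TMM factor, as mean ± standard deviation over the libraries of a group. Levels and sums used to find RNA of other tissue are CPM of the library total without that factor. Labels call the libraries replicate biosamples without naming animals, so the p-values measure the spread between these libraries.

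Lists of 4 kinds of epithelial genes, chosen after the data were seen, each summed to at most 129 CPM in 39 libraries, and at least 1 of them was abundant in each of the other 4. SD library 4 and SZ-A 600 library 6 held genes of ciliated epithelium, with Foxj1, the master regulator of motile cilia, at 274 and 433 CPM. The list summed to 1610.3 and 3062 CPM, against a median of 47.7 CPM in the other 39 libraries. SZ-A 400 library 6 held secretory genes of the vas deferens and epididymal duct, with Akr1b7 at 17872 CPM and Crisp1 at 9454 CPM. Its smooth muscle genes summed to 29279 CPM, while the other 3 of these libraries lay within the range of the 39, 669.5 to 2296 CPM. SZ-A 400 library 3 held genes of squamous and sebaceous epithelium, with the cystatin gene Cst6 at 9555 CPM and the keratin gene Krt14 at 674 CPM. These 4 libraries had 537, 752, 580 and 185 genes at over 20 times the median of all libraries. The next highest library, SZ-A 200 library 8, had 58, and its B and plasma cell markers summed to 12146 CPM. Epididymis markers of a list fixed before summed to 214 CPM in SD library 1. They summed to 193 and 148 CPM in SD library 4 and SZ-A 600 library 6. SD library 1 and SZ-A 200 library 8 stayed in the fits without libraries with other tissue RNA. Small noncoding RNA genes took 0.00319% to 0.00642% of the counts in 22 libraries (library set 1) and 0.00992% to 0.0228% in the other 21 (library set 2). The labels do not mention this split, which follows the library numbers. Set 1 held libraries 1 and 2 of SD and libraries 1 to 5 of each other group. With group and set as terms, limma-trend on log2 CPM called 6104 genes higher and 5443 lower in set 2, of 20218 tested. Sets 1 and 2 held 2 and 5 SD, 5 and 5 HFD, 5 and 4 SZ-A 200, 5 and 3 SZ-A 400, and 5 and 4 SZ-A 600 libraries. For HFD against SD, each dose against HFD and the trend, counts of called genes without the 4 libraries and within each set are given beside the pooled ones.

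**Figure D1:**
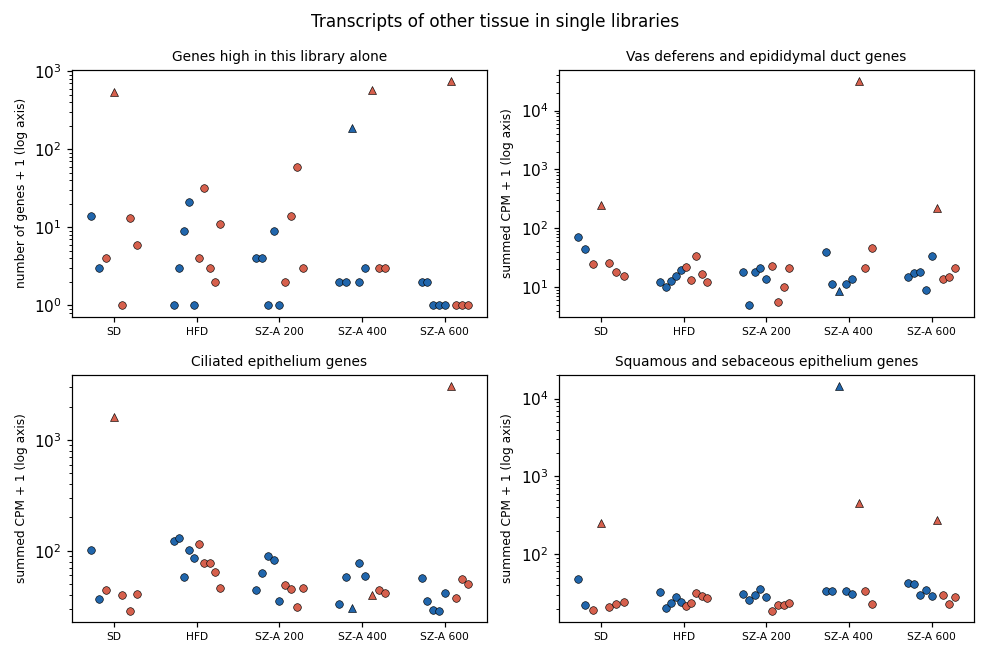
Each point is 1 library, in columns by group, and the log axes show the number of genes at over 20 times the median of all libraries plus 1, and the summed CPM plus 1 of genes of vas deferens and epididymal duct, of ciliated epithelium and of squamous and sebaceous epithelium. Blue circles are library set 1, red circles library set 2 and triangles the 4 libraries with RNA of other tissue, whose counts of such genes were 537, 185, 580 and 752 against at most 58 elsewhere.

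The comparison of HFD with SD asked what the high-fat diet alone changed in this fat pad. Most macrophage, lysosomal, cell-cycle and extracellular matrix genes tested rose, and part of the genes of insulin signalling, the circadian clock and branched-chain amino acid breakdown fell. With an estimated correlation camera called 0 of these 7 lists (adjusted p = 0.53 or 0.709). Adgre1, the gene of the macrophage surface protein F4/80, had 435 ± 285 CPM on HFD (n = 10) and 25.9 ± 10.9 CPM on SD (n = 7; log2 fold change 4.07, SE 0.78, adjusted p = 3.34e-04). In HFD library 8 it had 8.12 CPM, below the 14.1 to 38.7 CPM of the SD libraries, with Itgax at 9.15 and Trem2 at 8.09 CPM, so that library lacked the rise. Itgax, which encodes CD11c of inflammatory macrophages, rose by 5.36, adjusted p = 1.03e-04, and Trem2, the lipid-sensing receptor of lipid-associated macrophages, by 5.00, adjusted p = 4.7e-04 on the log2 scale. Lep, the gene of the satiety hormone leptin, rose from 459.8 ± 176 to 1725 ± 623 CPM (log2 fold change 1.91, SE 0.44, adjusted p = 0.0014). Col1a1, a fibrillar collagen gene, had a log2 fold change of 1.63, adjusted p = 0.0121.

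Counts per gene list gave the same picture in more detail. Of the macrophage markers, 19 of 20 rose (19 adjusted over the list alone), among them Cd68 (log2 fold change 3.94) and the complement gene C1qb (2.98). Of the lipid-associated macrophage markers, 16 of 20 rose (16 adjusted over the list alone). Of the lysosomal genes, 26 of 30 rose (29 adjusted over the list alone), with the glycosidase gene Gusb at 2.82 and the cathepsin gene Ctsa at 1.88. Of the proliferation genes, 29 of 30 rose (29 adjusted over the list alone), with the replication helicase gene Mcm5 at 2.29 and the mitotic kinase gene Cdk1 at 2.28. Of the extracellular matrix genes, 27 of 37 rose and 2 fell (27 up and 2 down adjusted over the list alone), with Col6a2 at 1.78 and the stromelysin gene Mmp3 at 3.95. Antigen presentation genes of MHC class II (8 of 11 rose, 8 adjusted over the list alone), type I interferon genes (11 of 22 rose, 11 adjusted over the list alone) and unfolded protein response genes (14 of 23 rose and 2 fell, 14 up and 3 down adjusted over the list alone) were also called higher as lists. Hspa5, the endoplasmic reticulum chaperone BiP, went from 289 ± 56.7 to 619 ± 153 CPM (log2 fold change 1.1, SE 0.17, adjusted p = 6.93e-05). Among insulin signalling genes, 2 of 21 rose and 11 fell (2 up and 12 down adjusted over the list alone), including the receptor gene Insr (-1.26) and its substrate gene Irs1 (-1.88). Among clock genes, 1 of 19 rose and 9 fell (1 up and 11 down adjusted over the list alone), including Hlf (-1.52). These 10 lists were called by camera with a preset correlation, and each had an adjusted p = 0.53 with an estimated correlation. Cytokine (12 of 29 rose and 1 fell, 12 up and 2 down adjusted over the list alone), resident macrophage (6 of 15 rose, 6 adjusted over the list alone) and ribosomal protein genes (28 of 73 rose, 52 up and 1 down adjusted over the list alone) were called higher. Called lower were branched-chain amino acid (8 of 22 fell, 10 adjusted over the list alone), endothelial (8 of 20 fell, 10 adjusted over the list alone) and erythroid genes (3 of 10 fell, 3 adjusted over the list alone). Each of these 6 lists had an adjusted p = 0.709 with an estimated correlation. Camera called 22 of the 46 lists, 14 higher and 8 lower, and fry called 14 (12 higher, 2 lower). With an estimated correlation it called 0 in this and in every other comparison. Recovery of a changed list was tested on simulated counts with the preset correlation alone. Whether camera with an estimated correlation could call a list in these data is therefore not known, and its adjusted p-values do not show that a list was unchanged.

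Adipocyte genes moved less evenly. Ppargc1a, a coactivator of mitochondrial biogenesis, fell from 11.9 ± 5.22 to 2.95 ± 1.14 CPM (log2 fold change -2.02, SE 0.41, adjusted p = 4.87e-04). Of the mature adipocyte markers, 2 of 20 fell (1 adjusted over the list alone), among them the activin receptor gene Acvr1c (-2.05). The list had an adjusted p = 0.714 with an estimated correlation and list medians of -1.33 in set 1 and -0.09 in set 2. Adipoq, the gene of adiponectin, was not called (-0.54, adjusted p = 0.301 on the log2 scale), nor was Pparg (-0.58, adjusted p = 0.157), Mest (0.73, adjusted p = 0.142), Fasn (0.04, adjusted p = 0.933) or Scd1 (-1.06, adjusted p = 0.0534). Sfrp5, a secreted Wnt inhibitor of adipocytes, rose by 1.47, adjusted p = 0.0065, and the cytokine genes Ccl2 and Tnf by 1.66, adjusted p = 0.0122 and 1.93, adjusted p = 0.009.

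In all, edgeR called 3725 genes higher and 2689 lower on HFD, 31.7% of the 20218 tested, of which 1893 and 1247 differed at least 2-fold. The 10 largest rises under the naming rule were Gpr50, Myh15, Tph2, Serpinb9b, Olfr111, Lipn, Itgad, Serpinb1c, Vsig8 and Gdf3, with log2 fold changes from 5.70 to 7.55. Gpr50, an orphan receptor gene related to the melatonin receptors (chromosome X, 70707273 to 70712863, as the files give it), went from 0.174 ± 0.343 to 35.4 ± 26.7 CPM. Tph2, which encodes a serotonin-synthesising hydroxylase, went from 0.401 ± 0.28 to 49.4 ± 38.3 CPM. Itgad, a leukocyte integrin gene, went from 0.304 ± 0.349 to 22.0 ± 15.5 CPM. Olfr111 belongs to a large family of similar genes, so its counts are uncertain. The 10 largest falls were Tmprss2, Greb1, Ano9, Cfap44, Adcy8, Slc27a2, Fermt1, Fgfr4, Ppp1r1b and Mapk15, with log2 fold changes from -8.69 to -6.00. Their SD means were carried by SD library 4. Without the libraries with other tissue RNA Fgfr4 was not called (-2.19, adjusted p = 0.0859), Tmprss2, Greb1 and Adcy8 were too low to be tested, and Cfap44 stood at -2.46 in place of -7.59. Without those libraries 4151 genes were higher and 3110 lower, within library set 1 3531 and 3794, and within set 2 202 and 146, and 1323 and 772 in set 2 without SD library 4 and the other libraries with other tissue RNA. Upper-quartile scaling shifted the median of all genes to -0.17 on the log2 scale from -0.05 and gave 2959 higher and 3501 lower, 45.8% against 58.1% higher.

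**Figure D2:**
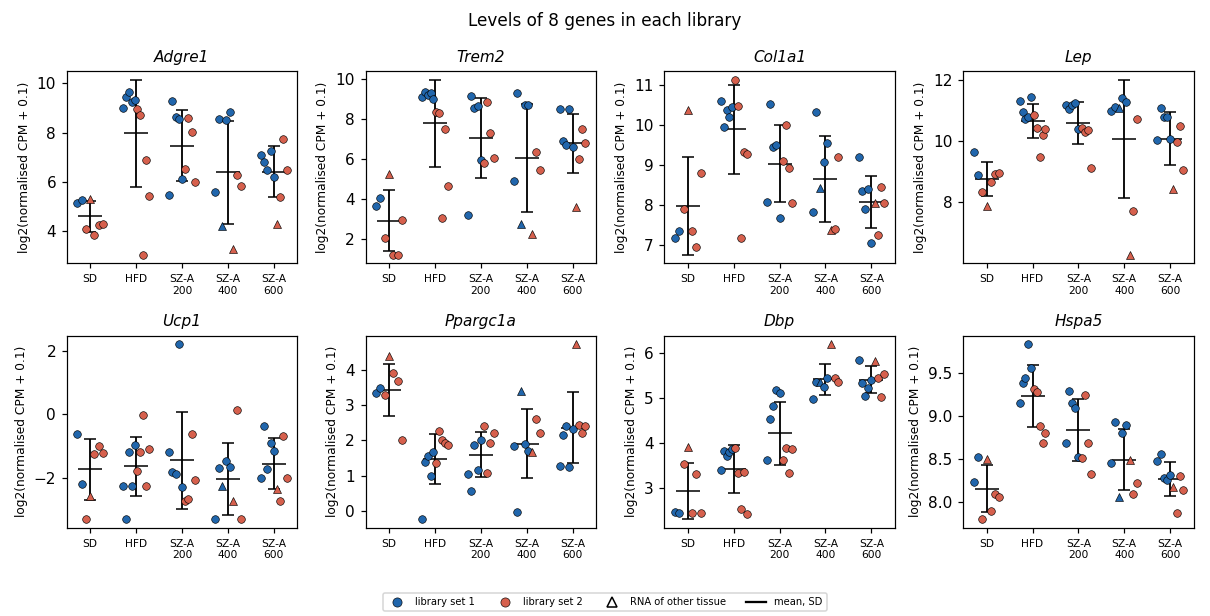
Each panel gives 1 gene's log2 normalised CPM per library in the 5 groups, with blue circles for library set 1, red circles for set 2, triangles for the 4 libraries with RNA of other tissue, and bars for the mean ± standard deviation. Adgre1, Trem2, Col1a1, Lep and Hspa5 were higher on HFD than on SD, Dbp rose with SZ-A 400 and 600, and Ucp1 lay near its floor throughout.

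SZ-A at 200 mg/kg/day moved 2 genes past the threshold against HFD. Nr1d2, which encodes the clock repressor REV-ERB beta, had 79.2 ± 9.32 CPM with SZ-A (n = 9) and 50.5 ± 8.04 CPM on HFD (log2 fold change 0.65, SE 0.12, adjusted p = 0.0312). It lay above the highest HFD library in 9 of 9 libraries. Ube3a, a ubiquitin ligase gene, had 60.6 ± 5.35 and 42.7 ± 7.76 CPM (log2 fold change 0.50, SE 0.09, adjusted p = 0.0312). No gene fell past the threshold in edgeR, where 534 genes were lower and 863 higher at an unadjusted p under 0.05, against 1010.9 expected in all. DESeq2 called 15 genes lower and limma voom 174.

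Camera called lists with a preset correlation alone. Of the clock genes, 1 of 19 rose (8 up and 2 down adjusted over the list alone), with Dbp at 0.88, adjusted p = 0.382 and an adjusted p = 0.47 for the list with an estimated correlation. Of the immediate early genes, which respond to stimuli within minutes, 0 of 20 were called (9 adjusted over the list alone), with Dusp1 at -0.79, adjusted p = 0.382 and Egr1 at -1.52, adjusted p = 0.476 and an adjusted p = 0.247 for the list with an estimated correlation. Macrophage (0 of 20 were called, 0 adjusted over the list alone), proliferation (0 of 30 were called, 0 adjusted over the list alone) and extracellular matrix genes (0 of 37 were called, 0 adjusted over the list alone) were called lower as lists. They had an adjusted p = 0.692, 0.679 and 0.47 with an estimated correlation. The macrophage list had a median of -0.98 in library set 1 and 0.16 in set 2. The mature adipocyte list was called higher (0 of 20 were called, 0 adjusted over the list alone, adjusted p = 0.679 with an estimated correlation), with medians of 1.09 and -0.32. In the list of NK, mast cell and granulocyte markers (0 of 18 were called, 0 adjusted over the list alone, adjusted p = 0.699 with an estimated correlation) the test pointed down with a median of -0.04 and a mean of 0.02. Camera called 25 of the lists, 11 higher and 14 lower, and fry called 0.

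The count at 200 mg/kg/day, of 2 genes near the threshold, changed when single libraries were left out. Leaving out 1 library at a time gave 0 without HFD libraries 1, 3, 4, 5 or 10 or SZ-A 200 libraries 3, 5, 6, 7, 8 or 9, 1 without SZ-A 200 library 1 and 5 without HFD library 8. Library set 1 alone gave 504 genes higher and 60 lower, set 2 alone gave 0 in edgeR (1279 at an unadjusted p under 0.05). With libraries of other tissue RNA left out, 7 genes were higher and 1 lower, and 64 and 85 with library set as a term as well. In edgeR 0 genes passed a test of the difference between the sets (lowest adjusted p = 0.18). At an unadjusted p under 0.05 it gave 3242 genes, against 1002.7 expected, so a difference between the sets was not excluded.

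Of the clock genes, 6 of 19 rose and 2 fell (10 up and 3 down adjusted over the list alone) with SZ-A at 400 mg/kg/day against HFD. Of the unfolded protein response genes, which include chaperones of the endoplasmic reticulum, 2 of 23 fell (5 adjusted over the list alone). These lists had an adjusted p = 0.152 and 0.208 with an estimated correlation. Dbp, a clock output transcription factor (chromosome 7, 45354512 to 45359627, as the files give it), had 43.9 ± 12.4 CPM (n = 8) against 11.2 ± 3.48 CPM (log2 fold change 1.97, SE 0.24, adjusted p = 1.16e-05). It lay above the highest HFD library in 8 of 8 libraries. The related Tef and Hlf rose by 0.97, adjusted p = 2.37e-04 and 2.21, adjusted p = 3.67e-04 on the log2 scale. Npas2, a clock activator, fell by 1.55 (adjusted p = 0.0135). Hspa5 had 369 ± 90.3 CPM against 619 ± 153 CPM (log2 fold change -0.75, SE 0.16, adjusted p = 0.00609). Creld2, another target of the unfolded protein response, had a log2 fold change of -0.80 (adjusted p = 0.00347).

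Without the libraries with other tissue RNA and with library set as a term, 6 clock genes rose and 1 fell, and 4 unfolded protein response genes fell. In that fit Dbp, Creld2 and Hspa5 stood at 1.78, -0.85 and -0.76 (adjusted p = 4.23e-05, 0.0063 and 0.00521), and Npas2 at -1.53 was not called (adjusted p = 0.0568). Leaving out those libraries without that term, 4 clock genes rose and 1 fell, and 1 unfolded protein response gene fell, with Dbp at 1.80, Creld2 at -0.84 and Hspa5 at -0.69 (adjusted p = 1.45e-04, 0.0109 and 0.14). Proliferation (0 of 30 were called, 24 adjusted over the list alone), extracellular matrix (1 of 37 fell, 2 up and 20 down adjusted over the list alone), macrophage (0 of 20 were called, 0 adjusted over the list alone), interferon (2 of 22 fell, 4 adjusted over the list alone) and cytokine genes (1 of 29 rose and 1 fell, 1 up and 3 down adjusted over the list alone) were called lower as lists. They had an adjusted p = 0.285, 0.152, 0.285, 0.152 and 0.152 with an estimated correlation. The macrophage score, a mean log2 CPM, was 4.24 and 3.97 in SZ-A 400 libraries 3 and 6 and 5.47 to 8.29 in the other 6. Medians of the 5 lists were -1.1, -0.75, -0.95, -0.43 and -0.82 with all libraries, and -0.98, -0.50, -0.78, -0.45 and -0.76 without the 4 libraries and with library set as a term, where their adjusted p was 0.435 to 0.454 with an estimated correlation. The naming rule took the falls Ifi206, Hmcn1, Adamts16, Arsi, Npas2, Ptx3, Btnl2, Nlrp3, Oas1g and Oas3, from -1.73 to -1.44. With libraries of other tissue RNA left out they stood at -1.96 to -1.23 and were not called, with an adjusted p from 0.12 to 0.35. Among them were the inflammasome gene Nlrp3 (-1.48) and the antiviral gene Oas3. Adgre1 (-1.31, adjusted p = 0.275), Ccl2 (-1.22, adjusted p = 0.157), Col1a1 (-1.18, adjusted p = 0.161) and Trem2 (-0.90, adjusted p = 0.589) were not called. Camera called 27 lists, 11 higher and 16 lower, and fry 6 (1 higher, 5 lower).

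Of the 498 genes higher at 400 mg/kg/day, 469 were highest in library 3 or 6. Among the 10 largest rises under the naming rule were Ano9, Prss8, Cnn1, S100a14, Kcnk1, Perp, Mal, Cldn3 and Sh3bgr, with log2 fold changes from 5.90 to 7.58. The smooth muscle gene Cnn1 had 222 ± 614 CPM, a spread larger than its mean, and the tight junction gene Cldn3 25.8 ± 64.9 CPM. Of the pericyte and smooth muscle markers, 7 of 14 rose (10 adjusted over the list alone) with an adjusted p = 0.285 with an estimated correlation. Of the skeletal muscle markers, 4 of 14 rose (7 adjusted over the list alone) with an adjusted p = 0.438 with an estimated correlation. Without the 4 libraries and with library set as a term, 1 and 0 of them rose. Without the 4 libraries and without that term, 0 of the 9 rises named here were called in edgeR. edgeR called 498 genes higher and 82 lower, and 8 and 3 without the libraries with other tissue RNA. A fit of the HFD and SZ-A 400 libraries alone called 6, library set 1 gave 659 and 166, and set 2 gave 82 and 4. Set 1 holds library 3 and set 2 library 6, and set 2 without libraries of other tissue RNA gave 0 in edgeR (2144 at an unadjusted p under 0.05). Leaving out 1 library at a time gave 90 without SZ-A 400 library 6, 316 without SZ-A 400 library 3, 340 without HFD library 3, 353 without HFD library 4, 358 without HFD library 6, 363 without HFD library 1, 373 without HFD libraries 2 or 7, 900 without SZ-A 400 library 5, 917 without HFD library 8 and 1218 without SZ-A 400 library 2.

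Most cell-cycle, extracellular matrix and B cell genes tested and part of the macrophage and unfolded protein response genes were lower with SZ-A at 600 mg/kg/day than on HFD, and clock genes moved both ways. With an estimated correlation camera called 0 of these 6 lists (adjusted p from 0.225 to 0.632). Adgre1 had 103 ± 58.9 CPM (n = 9) against 435 ± 285 CPM on HFD (log2 fold change -2.08, SE 0.64, adjusted p = 0.0307). Ccl2, a chemokine gene that attracts monocytes, had 5.81 ± 3.33 against 23.6 ± 10.9 CPM (log2 fold change -2.03, SE 0.47, adjusted p = 0.00906). Col1a1 had 294 ± 133 against 1148 ± 586 CPM (log2 fold change -1.96, SE 0.46, adjusted p = 0.00938). Hspa5 had 309 ± 41.7 CPM (log2 fold change -1.0, SE 0.15, adjusted p = 2.2e-04), below the lowest HFD library in 9 of 9 libraries. Dbp had 43.1 ± 9.09 CPM (log2 fold change 1.94, SE 0.24, adjusted p = 4.89e-06), above the highest HFD library in 9 of 9.

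Of the proliferation genes, 27 of 30 fell (29 adjusted over the list alone), among them the mitotic genes Kif23 (-1.68), Cenpf (-2.13) and Aurka (-1.40). Of the extracellular matrix genes, 24 of 37 fell (28 adjusted over the list alone), with Col6a3 at -1.58 and the fibrillin gene Fbn1 at -2.17. Of the cytokine genes, 9 of 29 fell (12 adjusted over the list alone), and of the interferon genes, 6 of 22 fell (9 adjusted over the list alone). Of the unfolded protein response genes, 8 of 23 fell (10 adjusted over the list alone), with Creld2 at -0.90, Manf at -0.91 and Calr at -0.77. Of the clock genes 8 of 19 rose and 3 fell (9 up and 3 down adjusted over the list alone), with Tef at 1.1, adjusted p = 1.02e-05, Hlf at 2.07, adjusted p = 6.58e-04 and Per3 at 1.25, adjusted p = 0.0191. Arntl, the clock activator BMAL1, and Nfil3, a repressor at the sites that Dbp, Tef and Hlf bind, both named after their values were seen, fell by 1.55 (adjusted p = 1.24e-07) and 1.70 (adjusted p = 0.0022). These 6 lists had an adjusted p = 0.225 with an estimated correlation. Of the macrophage markers 10 of 20 fell (13 adjusted over the list alone), of the lysosomal genes 9 of 30 fell (17 adjusted over the list alone) and of the MHC class II genes 2 of 11 fell (8 adjusted over the list alone), each with an adjusted p = 0.546 with an estimated correlation. The macrophage list had medians of -1.62 in set 1 and -1.0 in set 2. Library 6 had the lowest macrophage score at 600 (4.35), and the other SZ-A 600 libraries of set 2 had 5.33 to 7.03, within the 5.09 to 7.81 of the HFD libraries of set 2. Of the resident macrophage markers, 5 of 15 fell (8 adjusted over the list alone), with an adjusted p = 0.328. The macrophage marker Cd14 (-1.41) and the resident marker Folr2 (-2.13) were among the genes that fell.

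Genes of lipid-associated macrophages were called lower as a list although 0 of 20 were called (0 adjusted over the list alone), with an adjusted p = 0.64 with an estimated correlation. None passed the test alone, with Trem2 at -1.28, adjusted p = 0.269 and Itgax at -1.22, adjusted p = 0.2. Of the B and plasma cell markers 11 of 17 fell (14 adjusted over the list alone), with an adjusted p = 0.632 with an estimated correlation. They included the B cell gene Ms4a1 (-3.54) and the light chain gene Igkc (-3.10), from HFD levels that varied widely (311 ± 446 CPM for Igkc). In CPM of the library total, these markers summed to 4028 and 3584 in HFD libraries 4 and 7. The other HFD libraries had 282 to 1412 CPM, and the SZ-A 600 libraries 129 to 472 CPM. Of the branched-chain amino acid genes 5 of 22 rose (8 adjusted over the list alone), with Aldh6a1 at 0.96 and an adjusted p = 0.578 with an estimated correlation. Of the mitochondrially encoded genes 2 of 15 rose (8 adjusted over the list alone), with an adjusted p = 0.49 with an estimated correlation. Its median was 1.47 in set 1 and 0.06 in set 2. Of the mature adipocyte markers 3 of 20 rose (3 adjusted over the list alone), with an adjusted p = 0.584 with an estimated correlation. It had medians of 1.30 and -0.09 in sets 1 and 2, and the glucose transporter gene Slc2a4 at 0.76. Lep (-0.47, adjusted p = 0.435), Adipoq (0.84, adjusted p = 0.132), Scd1 (1.11, adjusted p = 0.0638) and Fasn (-0.61, adjusted p = 0.199) were not called. Camera called 25 lists, 9 higher and 16 lower, and fry 9 (2 higher, 7 lower).

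The naming rule took as falls the immunoglobulin variable genes Igkv17-121, Igkv3-2, Igkv12-44, Ighv1-53, Ighv3-6 and Igkv6-17 and the genes Nptx1, Cck, Mmp10 and Hmga2, from -8.07 to -3.29. Variable genes share near-identical sequence, so their single values are uncertain. HFD means of some of these genes were carried by 1 library. Igkv17-121 and Mmp10 had 33.2 and 7.87 CPM in HFD library 10 against at most 4.84 and 0.645 CPM in the other HFD libraries, and Igkv6-17 had 12.7 CPM in HFD library 4 against at most 1.67 CPM. With libraries of other tissue RNA left out Mmp10 had a similar log2 fold change (-3.26) and was not called (adjusted p = 0.0542). Nptx1, a neuronal pentraxin gene (chromosome 11, 119429545 to 119438579, as the files give it), had 0.611 ± 0.462 against 7.91 ± 5.24 CPM, and Hmga2, a chromatin protein gene of growing cells, 0.778 ± 0.754 against 7.65 ± 4.00 CPM. As rises the rule took Ppp1r1b, Cfap52, Prss8, Slc30a2, Rdh16, Ppp1r36, Rbm11, Large2, Kif6 and Map3k21, from 4.47 to 6.43, whose group means were carried by library 6. Of these, Cfap52, Rdh16 and Map3k21 were also called without the libraries with other tissue RNA, at 2.21, 1.37 and 1.65 on the log2 scale, and Kif6 was too low to be tested.

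edgeR called 1036 genes higher and 1308 lower at 600 mg/kg/day, and 775 and 1502 without the libraries with other tissue RNA. Library set 1 alone gave 3385 and 2584, and set 2 alone 4 and 0. The set 2 value was 0 without other tissue RNA (edgeR, 1621 genes at an unadjusted p under 0.05), and 0 genes passed a test of the difference between the sets (1867 at an unadjusted p under 0.05, against 1002.7 expected, lowest adjusted p = 0.532). Leaving out 1 library at a time gave 1130 without SZ-A 600 library 6, 1276 without HFD library 3, 1458 without HFD library 4, 1530 without HFD library 5, 1558 without SZ-A 600 library 7 and 3963 without HFD library 8. Upper-quartile scaling moved the median of all genes from 0.06 to 0.11 on the log2 scale and gave 1136 higher and 1058 lower.

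**Figure D3:**
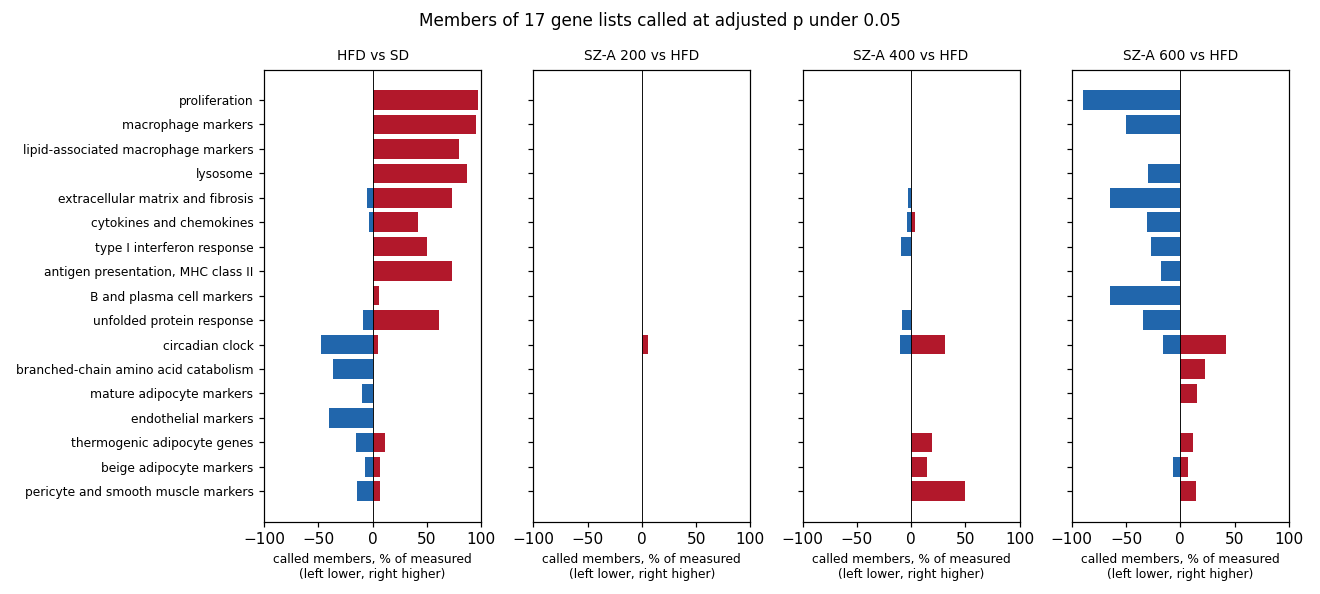
Horizontal bars give the percentage of each list's measured members called lower (left) or higher (right) by edgeR in HFD against SD and in each SZ-A dose against HFD. Proliferation genes went from 29 of 30 higher on HFD to 27 of 30 lower with SZ-A 600, and smooth muscle genes summed highest in SZ-A 400 library 6.

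Across the 4 high-fat groups, in a linear trend over dose, the clock genes Dbp, Tef and Nr1d2 rose and the chaperone gene Hspa5 fell. Dbp rose by 0.69 per step of 200 mg/kg/day on the log2 scale (SE 0.08, adjusted p = 2.48e-07), Tef by 0.38, adjusted p = 1.7e-06 and Nr1d2 by 0.29, adjusted p = 8.98e-06, and Hspa5 had a slope of -0.33, adjusted p = 8.76e-05. Mean Hspa5 levels were 619, 469, 369 and 309 CPM from HFD to SZ-A 600, beside 289 CPM on SD. In all 1379 genes rose and 1590 fell with dose, and 711 and 1403 without the libraries with other tissue RNA. The naming rule took Prss8, Ppp1r1b, Cfap52, Ppp1r36 and Slc30a2 as rises, of which Cfap52 alone was also called without those libraries, and Igkv17-121, Igkv3-2, Ighv3-6, Ighv1-53 and Igkv12-44 as falls. Library set 1 alone gave 3141 and 2389 genes and set 2 alone 4 and 0, or 2 and 0 without libraries of other tissue RNA. Leaving out 1 library at a time gave 1333 without SZ-A 600 library 6, 1836 without HFD library 3 and 1972 without HFD library 4.

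Direct comparisons of the doses found few differences beyond the other tissue RNA. Between 600 and 200 mg/kg/day edgeR called 0 genes (2454 at an unadjusted p under 0.05, lowest adjusted p = 0.0937), DESeq2 81 and limma voom 1269. Leaving out 1 library gave 1 without SZ-A 200 library 5 or SZ-A 600 library 6. Dbp stood at 1.06, adjusted p = 0.0937, Tef at 0.58, adjusted p = 0.0937 and Hlf at 1.03, adjusted p = 0.184 there. Between 400 and 200 mg/kg/day, 208 genes were higher and 2 lower, led by Kcnk1, Prss8, Asprv1, Ano9 and S100a14 from 6.33 to 7.08, with Glipr2 lower (-0.75, adjusted p = 0.0275). Between 600 and 400 mg/kg/day, 2 were higher and 103 lower, led by Mybpc1, Pkp1, Liph, Nrn1 and Plch2 from -7.67 to -4.05. Without the libraries with other tissue RNA both counts were 0 in edgeR, with 538 and 502 genes at an unadjusted p under 0.05. Dbp was higher at 400 than at 200 mg/kg/day (1.09, adjusted p = 0.0219), and stood at 0.96 without those libraries and with library set as a term, where it was not called (adjusted p = 0.889). For 400 against 200 mg/kg/day, leaving out 1 library at a time gave 24 without SZ-A 400 library 6, 73 without SZ-A 200 library 7, 76 without SZ-A 200 library 3, 84 without SZ-A 200 library 2, 100 without SZ-A 200 library 4, 101 without SZ-A 200 libraries 1 or 8, 104 without SZ-A 200 library 5, 121 without SZ-A 400 library 3, 136 without SZ-A 200 library 9 and 138 without SZ-A 200 library 6. For 600 against 400 mg/kg/day it gave 26 without SZ-A 400 library 6, 52 without SZ-A 600 library 3, 59 without SZ-A 600 library 2, 60 without SZ-A 600 library 5, 62 without SZ-A 600 library 7, 63 without SZ-A 600 library 4, 68 without SZ-A 600 libraries 8 or 9, 165 without SZ-A 400 library 8, 173 without SZ-A 400 library 5, 175 without SZ-A 400 library 4, 177 without SZ-A 400 library 1, 178 without SZ-A 400 library 2, 183 without SZ-A 400 library 7 and 203 without SZ-A 600 library 6.

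Genes of thermogenic fat, the subject of the series title, showed few changes. Ucp1, the uncoupling protein of brown and beige fat (ENSMUSG00000031710, chromosome 8, 84016981 to 84025081, as the files give it), lay near its floor, with a median of 7 counts per library and a highest level of 4.53 CPM in SZ-A 200 library 4. Its means were 0.254 ± 0.199 CPM on SD, 0.283 ± 0.251 on HFD, and 0.681 ± 1.45, 0.230 ± 0.328 and 0.289 ± 0.214 at 200, 400 and 600 mg/kg/day. It was not called in any comparison (0.03, adjusted p = 0.983 for 600 against HFD). Of the thermogenic list, 3 of 26 rose and 4 fell (2 up and 4 down adjusted over the list alone) on HFD against SD, 0 of 26 were called (0 adjusted over the list alone) at 200, 5 of 26 rose (6 adjusted over the list alone) at 400 and 3 of 26 rose (3 adjusted over the list alone) at 600. Leaving out the libraries with other tissue RNA, with library set as a term, edgeR called 0 at 400, and 3 rose and 2 fell at 600. Camera called the list in none of the 4 (adjusted p = 0.702, 0.194, 0.209 and 0.302). Ppargc1a rose at 600 (6.74 ± 7.53 CPM, log2 fold change 1.19, SE 0.39, adjusted p = 0.0394), where library 6 alone had 26.6 CPM. Without the libraries with other tissue RNA it was not called (0.52, adjusted p = 0.255). Cidea, a lipid droplet gene, rose at 400 (2.23, adjusted p = 0.00609), where library 3 had 66.5 CPM. Without those libraries it stood at 0.64 (adjusted p = 0.537). Prdm16, a transcription factor of brown fat identity, rose at 400 (0.71, adjusted p = 0.0304), with 0.58 and an adjusted p = 0.309 without them, and had 0.51, adjusted p = 0.0584 at 600. Dio2 (-1.02, adjusted p = 0.445), Elovl3 (-1.63, adjusted p = 0.176), Cox8b (-0.37, adjusted p = 0.6) and Adrb3 (0.03, adjusted p = 0.983) were not called at 600. Adrb3 on HFD varied from library to library (398 ± 637 CPM), with 1986 CPM in HFD library 8. Within library set 1 alone edgeR called Adrb3 higher at 200 (2.14, adjusted p = 0.0494). Its trend over dose there was 0.71 per step (edgeR, adjusted p = 0.00876). Both values were opposite in sign to those of all libraries. Of the beige adipocyte markers, 1 of 14 rose and 1 fell (1 up and 1 down adjusted over the list alone) at 600, with an adjusted p = 0.949 with an estimated correlation.

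Genes that the diet changed tended to go the other way with SZ-A. Of the 6414 genes called between HFD and SD, 2, 237 and 1746 were called in the opposite direction at 200, 400 and 600 mg/kg/day and 0, 2 and 6 in the same direction. Hspa5, Adgre1, Ccl2 and Col1a1 were among those opposite at 600. Both comparisons share the HFD libraries. Permuted residuals of all libraries, tested with limma, gave 0, 0 and 0 opposite genes over 100 draws in which no group differed. Few genes can be called there in either comparison, so these counts of 0 show little about a reversal. With the diet effect kept in, at most 349, 243 and 1 were opposite, while the counts of the data came from edgeR. Independent lists of these sizes would share 0.266, 81.3 and 379. With the HFD libraries split, so that odd-numbered ones served the diet comparison and even-numbered ones the dose, the counts were 0, 1 and 12, and 0, 1 and 205 the other way round. The dose comparisons of this split called 0, 3 and 33 genes in all, and 0, 4 and 610 the other way round. At 600 mg/kg/day 4 and 0 genes were called in the same direction. Across genes, which are not independent replicates, the covariance of the log2 fold changes was -0.207, -0.349 and -0.429, beside simulated means of -0.060, -0.068 and -0.068 from shared libraries alone (ranges of 100 draws -0.157 to 0.019, -0.267 to 0.003 and -0.210 to 0.022). With the HFD libraries split, which leaves no shared library, it was -0.090, -0.250 and -0.339, and -0.243, -0.367 and -0.437 the other way round. For 400 and 600 together, 213 genes were called in the same direction, beside 30.8 for independent lists, with a covariance of 0.245 beside a simulated mean of 0.072 and within the simulated range, -0.046 to 0.299. Within library set 1 the opposite counts were 418, 563 and 3915, and within set 2 they were 0, 6 and 1. In set 2 alone, 348 genes were called for the diet and 0, 86 and 4 for the doses. Without the libraries with other tissue RNA the opposite counts were 6, 9 and 1634.

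A score of the diet's signature gave each library 1 value. The signature held 3447 genes higher and 2676 lower in the odd-numbered HFD libraries than on SD, and the even-numbered HFD libraries served as the comparison group. The score was -1.28 ± 0.31 on SD (n = 7), 1.18 ± 1.59 on HFD (n = 5), and 0.80 ± 1.12, 0.44 ± 1.22 and 0.07 ± 0.75 at 200, 400 and 600 mg/kg/day. Differences from HFD were -0.38 (exact permutation test, two-sided, p = 0.603), -0.74 (p = 0.339) and -1.11 (p = 0.0979), with adjusted p = 0.603, 0.508 and 0.294 over the 3 doses in the exact permutation test. At 600, 9 of 9 libraries lay below the HFD median. With odd and even HFD libraries exchanged, the difference at 600 was -1.72 (exact permutation test, adjusted p = 0.015), and over the other alternatives its adjusted p ranged from 0.204 to 0.385. Within library set 1 the differences were -1.45, -1.58 and -2.12 (exact permutation test, p = 0.0952, 0.0952 and 0.0476, the last being the smallest possible with 2 HFD libraries), and within set 2 they were 0.13, -0.76 and -0.67 (exact permutation test, p = 0.914, 0.5 and 0.457).

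**Figure D4:**
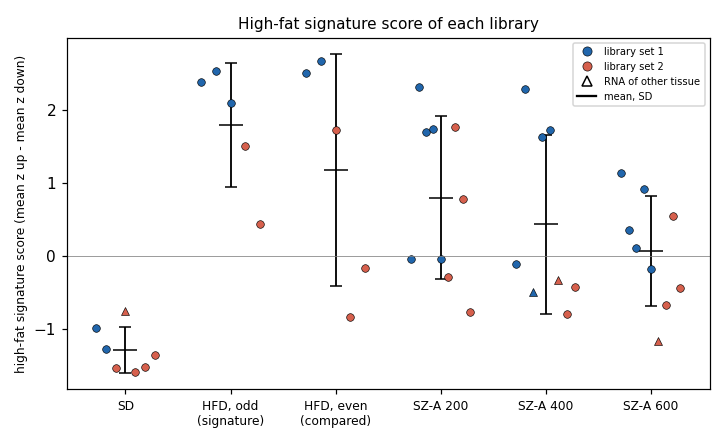
Each point is the diet signature score of 1 library, with SD, odd-numbered HFD libraries (used to define the signature), even-numbered HFD libraries (compared) and SZ-A 200, 400 and 600 in columns. Blue circles are library set 1, red circles set 2, triangles the 4 libraries with RNA of other tissue, and bars the mean ± standard deviation. Means were 1.18 in the compared HFD libraries and 0.07 at SZ-A 600, and 0 of the 3 differences passed the exact permutation test after adjustment.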

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

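The tests of other tissue RNA, of library set, of macrophage share as the whole cause, of the hour of collection, the splits of HFD and SD libraries and the splits within library sets were chosen after the results were seen. Every setting with library set or without libraries of other tissue was also added then.

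Of the 498 genes higher with SZ-A 400 than with HFD, 469 were highest in library 3 or 6, and 1.2% (6 genes) were still called higher without these libraries, so RNA of other tissue in them is a likely source of most rises. With library set as a term 94.6% were still called, which speaks against an imbalance of library sets. A response of the fat tissue stayed open, as 41.2% had a median in the 6 other SZ-A 400 libraries above HFD by over 1 standard deviation of HFD. The median log2 fold change was 2.52 in all libraries and the difference of medians 0.41 in those 6.

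The list of vas deferens and epididymal duct genes holds 12 genes, of which 2 were expressed in the 39 other libraries (median of at least 1 CPM) and 8 are also in a list fixed before. In SZ-A 400 library 6 it summed to 31895 CPM, led by Akr1b7 (17872 CPM) and Crisp1 (9454 CPM), against at most 71.2 CPM in those 39, and 250.1 and 223 CPM in SD library 4 and SZ-A 600 library 6. The 14 squamous and sebaceous genes, 5 of them expressed elsewhere and 0 in a fixed list, summed to 14451 CPM in SZ-A 400 library 3, led by Cst6 (9555 CPM) and Awat2 (1063 CPM). The 15 ciliated genes, 2 of them expressed elsewhere and 0 in a fixed list, were led in SZ-A 600 library 6 by Cfap65 (669.5 CPM) and Cfap44 (591 CPM).

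SZ-A 600 moved many genes within library set 1 and few within set 2. Set 2 without libraries of other tissue RNA still called 0 genes in edgeR, with 1621 at an unadjusted p under 0.05. That fit held fewer SZ-A 600 libraries, so it could not decide whether other tissue RNA in SZ-A 600 library 6 was a cause. A wider spread in set 2 stayed open, with a median standard error 1.42 times that of set 1, and 1.28 times without libraries with other tissue RNA in set 2. A standard error also grows with fewer libraries, and set 2 held 4 SZ-A 600 libraries against 5 in set 1. These ratios therefore do not measure spread alone. A smaller difference in set 2 may contribute, as the median difference of 4959 genes was 0.471 times that of set 1 (0.39 against 0.83). These genes were chosen by their call in a fit of both sets, so their direction within a set shows nothing further. That choice can favour genes that differed more in set 1, which held more SZ-A 600 libraries, so the ratio may be too low. The HFD macrophage score was 8.43 in set 1 and 6.54 in set 2. A test of whether SZ-A acted differently in the sets passed for 0 genes in edgeR. At an unadjusted p under 0.05 it gave 1867, against 1002.7 expected, so such a difference was not excluded.

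The 11 clock genes called with SZ-A 600 went the same way in both sets. They were chosen by their call in a fit of both sets, so this agreement shows nothing further. In sign 8 of them were opposite to HFD against SD, among them Arntl, which barely differed there (0.03, adjusted p = 0.921). Dbp (0.44, adjusted p = 0.183), Nfil3 (-0.43) and Npas2 (-0.12) had the same sign in both. With library set as a term 100% kept their call, which speaks against a set imbalance. With the macrophage score as a term their median difference was 0.708 times as large and 72.7% (8 of 11) kept their call, while all calls dropped to 226. The score thus did not account for the whole shift. A mean of marker genes is not the macrophage share itself, so a lower share as the whole or a partial cause stayed open. The labels give an hour of collection for 0 libraries, so a different hour between the groups could cause such a shift and stayed open. A response of the clock to SZ-A is a hypothesis with that limit.

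Other splits of the same libraries into groups of these sizes, 100 per comparison with the real one included, were counted for each result. For HFD against SD 1 gave as many genes as the real 6414 (highest other 2105), and 20 as many lists as 22 (highest other 29), so chance was not excluded for the lists. For SZ-A 200, 4 gave 2 genes or more (highest other 3620), 3 as many opposite genes (3219) and 9 as many lists as 25 (29). For SZ-A 400, 2 gave 580 genes or more (highest other 1344), 3 gave 237 opposite genes or more (436) and 10 gave 27 lists or more (33). For SZ-A 600, 1 gave 2344 genes (highest other 499), 1 gave 1746 opposite genes (297) and 3 gave 25 lists or more (28). For the dose trend 2 gave 2969 genes or more (highest other 4427). For 600 against 200 the real count was 0, so all 100 reached it (highest other 0) and nothing was tested. For 400 against 200 10 gave 210 or more (3393), and for 600 against 400 41 gave 105 or more (1945). These splits ignored library set, so 100 splits that kept the number of libraries of each set in each group were drawn as well. There 1 gave 6414 genes for HFD against SD (highest other 1), 4 gave 2 or more for SZ-A 200 (2205), 2 gave 580 or more for SZ-A 400 (1181), 1 gave 2344 for SZ-A 600 (0), and 1 gave 2969 for the trend (1807). For 600 against 200 all 100 again reached 0 (1). For 400 against 200 4 gave 210 or more (1815), and for 600 against 400 39 gave 105 or more (827). Opposite counts were reached by 3, 1 and 1 splits at 200, 400 and 600 mg/kg/day (highest others 1279, 75 and 0), and list counts by 27, 12, 17 and 5 for HFD against SD and the 3 doses (28, 27, 32 and 27). In both kinds of splits chance was excluded at 1 in 20 for the gene counts of HFD against SD, SZ-A 600 and the trend. The same held for the opposite count at 600. Other splits there called a median of 0 genes in both kinds, so few genes could be opposite in them. That count therefore repeats the test of the gene count and shows nothing further about direction. Nothing was adjusted over the results tested. The counts of SZ-A 400 passed too, but fell to 11 genes and 9 opposite genes without libraries of other tissue RNA. No splits were drawn without those libraries, so chance was not tested for the remaining genes. The counts of SZ-A 200 also passed in both, but rest on 2 genes, and edgeR called 0 genes when any 1 of 11 libraries was left out. Lists at SZ-A 600 passed in the first kind alone and 400 against 200 in the second kind alone, so chance stayed open there. It was not excluded for the other lists or for 600 against 400. Splits with several times the real count, for SZ-A 200, 400 against 200 and 600 against 400, point to a structure among the libraries. The highest other splits for SZ-A 400, the trend, 400 against 200 and 600 against 400 had shares of set 2 that differed by -0.8, 0.689, -0.778 and -0.639. Splits within library sets also exceeded the real count for SZ-A 400, 400 against 200 and 600 against 400. Library set alone therefore does not account for this structure, and the placing of libraries with other tissue RNA was not tested. With library set as a term the real counts were 1274, 5082, 149 and 54.

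Libraries far from the others of their group were found in 31 of 160 groups of values tested, where chance gives about 1 in 20, or 8. In SZ-A 400 library 6, with RNA of the vas deferens, log2 CPM was low for Adipoq (7.94, median of the others 11.19), Mest (4.97, 9.01) and Pparg (4.26, 7.32). There mature adipocyte markers had a mean log2 CPM of 7.29 (9.94), smooth muscle markers 8.27 (4.89) and epididymis markers 3.85 (-0.51), with 580 private genes (2). In SZ-A 600 library 6 Adipoq was at 9.77 (11.85), Pparg at 5.91 (7.30), Itgax at 3.87 (7.03), Ppargc1a at 4.73 (2.25), mature adipocyte markers at 9.07 (10.39) and clock genes at 5.43 (4.79), with 752 private genes (0). In SD library 4 Adipoq was at 9.62 (11.41), Pparg at 6.15 (7.87), Dio2 at 1.41 (-2.63) and mature adipocyte markers at 8.84 (10.52), mitochondrially encoded genes took 3.22% of the counts (5.19%), and 537 genes were private (4). SZ-A 400 library 3 had Cidea at 6.06 (1.90). HFD library 8 had Col1a1 at 7.18 (10.36), Dio2 at -4.24 (0.91), Tnf at -1.49 (1.29) and 11.4% mitochondrially encoded counts (2.25%). HFD library 7 had B and plasma cell markers at 5.43 (1.1), HFD library 1 Ppargc1a at -0.33 (1.66), and SD library 1 epididymis markers at 3.41 (-0.30). SZ-A 200 library 9 had Lep at 9.13 (10.75), library 4 Ucp1 at 2.20 (-2.27) and library 8 58 private genes (2.5).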

How the results depend on the processing

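The settings with library set, with libraries of set 1 or 2 alone, or without libraries of other tissue were chosen after the results were seen. Values that moved by over 1.5 times or passed a threshold are given against the numbers of the report. Stricter thresholds lower counts by construction and smaller sets of libraries hold fewer libraries. For the other settings the cause was not tested. Beside counts of 0, parentheses give genes at an unadjusted p under 0.05. Depth limits Ucp1, with a median of 7 counts per library. With adjusted p under 0.05 and at least 2-fold, gene counts were 3140 for HFD vs SD, 0 for SZ-A 200, 1112 for SZ-A 600, 346 for dose trend. With adjusted p under 0.01, gene counts were 3462 for HFD vs SD, 0 for SZ-A 200, 154 for SZ-A 400, 298 for SZ-A 600, 630 for dose trend, 39 for 400 vs 200, 28 for 600 vs 400. With limma voom with quality weights, gene counts were 13817 for HFD vs SD, 483 for SZ-A 200, 896 for SZ-A 400, 8933 for SZ-A 600, 8437 for dose trend, 1269 for 600 vs 200, 0 (1184) for 400 vs 200, 2 for 600 vs 400, and opposite counts were 402 for SZ-A 200, 727 for SZ-A 400, 7143 for SZ-A 600. With library set 2 only, gene counts were 348 for HFD vs SD, 0 (1279) for SZ-A 200, 86 for SZ-A 400, 4 for SZ-A 600, 4 for dose trend, 0 (2461) for 400 vs 200, 0 (1326) for 600 vs 400, and opposite counts were 0 for SZ-A 200, 6 for SZ-A 400, 1 for SZ-A 600, and list counts were 14 for HFD vs SD, 8 for SZ-A 200. With library set 2 only, without libraries with other tissue RNA, gene counts were 2095 for HFD vs SD, 0 (1842) for SZ-A 200, 0 (2144) for SZ-A 400, 0 (1621) for SZ-A 600, 2 for dose trend, 0 (1082) for 400 vs 200, 0 (369) for 600 vs 400. With DESeq2 size factors in edgeR, gene counts were 0 (1390) for SZ-A 200. With the DESeq2 Wald test, gene counts were 26 for SZ-A 200, 81 for 600 vs 200, and opposite counts were 18 for SZ-A 200, 381 for SZ-A 400. With limma-trend on log2(FPKM + 1), gene counts were 0 (1446) for SZ-A 200, 44 for SZ-A 400, 1901 for dose trend, 0 (992) for 400 vs 200, 0 (741) for 600 vs 400. With limma-trend on log2(FPKM + 0.1), gene counts were 0 (1433) for SZ-A 200, 34 for SZ-A 400, 1871 for dose trend, 0 (997) for 400 vs 200, 0 (740) for 600 vs 400. With no filter beyond 1 count, gene counts were 0 (3422) for SZ-A 200, 333 for 400 vs 200, 182 for 600 vs 400. With the stricter filter, gene counts were 6 for SZ-A 200, 93 for 400 vs 200, 55 for 600 vs 400. With library set as a term, gene counts were 9 for SZ-A 200, 1274 for SZ-A 400, 4329 for SZ-A 600, 5082 for dose trend, 19 for 600 vs 200, 54 for 600 vs 400, and opposite counts were 8 for SZ-A 200, 706 for SZ-A 400, 3057 for SZ-A 600. With library set 1 only, gene counts were 564 for SZ-A 200, 5969 for SZ-A 600, 5530 for dose trend, 2 for 600 vs 200, 0 (1163) for 400 vs 200, 0 (1953) for 600 vs 400, and opposite counts were 418 for SZ-A 200, 563 for SZ-A 400, 3915 for SZ-A 600. Without libraries with other tissue RNA, gene counts were 8 for SZ-A 200, 11 for SZ-A 400, 1 for 600 vs 200, 0 (538) for 400 vs 200, 0 (502) for 600 vs 400, and opposite counts were 6 for SZ-A 200, 9 for SZ-A 400. Without libraries with other tissue RNA, library set as a term, gene counts were 149 for SZ-A 200, 61 for SZ-A 400, 4985 for SZ-A 600, 4789 for dose trend, 16 for 600 vs 200, 0 (853) for 400 vs 200, 0 (913) for 600 vs 400, and opposite counts were 115 for SZ-A 200, 48 for SZ-A 400, 3637 for SZ-A 600. Without SZ-A 400 libraries 3 and 6, gene counts were 6 for SZ-A 200, 10 for SZ-A 400, 0 (430) for 400 vs 200, 0 (1142) for 600 vs 400. With groups of the comparison only, gene counts were 6 for SZ-A 400, 0 (1046) for 400 vs 200, 0 (920) for 600 vs 400, and opposite counts were 4 for SZ-A 400. With the signature from even-numbered HFD libraries, score differences were -1.72 for SZ-A 600 (exact permutation test, adjusted p = 0.015). With odd-numbered HFD libraries for the diet comparison, opposite counts were 0 for SZ-A 200, 1 for SZ-A 400, 12 for SZ-A 600. With even-numbered HFD libraries for the diet comparison, opposite counts were 0 for SZ-A 200, 1 for SZ-A 400, 205 for SZ-A 600. With camera with estimated correlation, list counts were 0 for HFD vs SD, 0 for SZ-A 200, 0 for SZ-A 400, 0 for SZ-A 600. With fry, list counts were 14 for HFD vs SD, 0 for SZ-A 200, 6 for SZ-A 400, 9 for SZ-A 600.

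A turn of sign was counted only for values called in the main fit or in the alternative. Of these, 6 turned: Fgfr4, HFD against SD, 0.31 and Cidea, SZ-A 400, -0.0552 and Plch2, 600 against 400, 0.0757 in set 2 without other tissue RNA, Adrb3, SZ-A 200, 2.14 in set 1, and the Adrb3 trend 0.67 with limma voom and 0.71 in set 1. Of 2665 values of named genes under the settings fixed before, 2324 kept their side of the threshold, 281 lost the call, 59 gained a call and 1 turned. Values called in neither fit were counted as kept whatever their sign. Under the settings added later these were 1353, 347, 42 and 5 of 1747.

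Leaving out 1 library at a time gave these lowest and highest values: HFD vs SD 5325 to 7518, SZ-A 200 0 to 5, SZ-A 400 90 to 1218, SZ-A 600 1130 to 3963, dose trend 1333 to 4382, 600 vs 200 0 to 1, 400 vs 200 24 to 295, 600 vs 400 26 to 203.

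Replicate numbers do not pair the libraries: 10 of 43 matched best a library with their own number, and the mean correlation with the same number was 0.165, against 0.202 with other numbers of the same library set. With the replicate block, gene counts were 10172 for HFD vs SD, 1 for SZ-A 200, 3736 for SZ-A 600, 1 for 600 vs 200, 0 (1522) for 400 vs 200, 0 (936) for 600 vs 400, and opposite counts were 1 for SZ-A 200, 536 for SZ-A 400, 3093 for SZ-A 600.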

Other observations

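The settings and gene lists of this part that use library set or leave out other tissue RNA were chosen after the data were seen.

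Of the erythroid markers at SZ-A 200, 0 of 10 were called (7 adjusted over the list alone), with list medians of 2.42 in library set 1 and -0.69 in set 2 and an adjusted p = 0.47 with an estimated correlation. Of the cholesterol genes on HFD against SD, 10 of 24 rose and 1 fell (12 up and 1 down adjusted over the list alone), among them the reductase gene Dhcr7 (2.04), with an adjusted p = 0.66 with an estimated correlation. Of the immediate early genes at SZ-A 600, 3 of 20 fell (5 adjusted over the list alone), with Socs3 at -1.33 and an adjusted p = 0.49 with an estimated correlation. Of the heat shock genes 4 of 12 fell (6 adjusted over the list alone), with Hspa1a at -2.81 and an adjusted p = 0.546 with an estimated correlation.

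Without the libraries with other tissue RNA and with library set as a term, 64 genes were higher and 85 lower at SZ-A 200, and 38 and 23 at SZ-A 400. The same naming rule took at SZ-A 200 the rises Alox12 (1.19, adjusted p = 0.0222), Klb, a coreceptor gene of FGF21 (1.14, adjusted p = 0.0458), and Fgf10 (0.99, adjusted p = 0.032), and falls such as Dusp1 (-0.80, adjusted p = 0.032) and Arntl (-0.70, adjusted p = 0.0245). At SZ-A 400 it took Dbp (1.78, adjusted p = 4.23e-05), Hlf (1.51, adjusted p = 0.00961) and Alox12 (1.76, adjusted p = 5.62e-04) as rises. As falls it took Arntl (-1.17, adjusted p = 5.62e-04), Creld2 (-0.85, adjusted p = 0.0063), Manf (-0.85, adjusted p = 0.00212) and Hspa5 (-0.76, adjusted p = 0.00521).

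Single libraries were set against the range of the HFD libraries. Dbp lay above the highest HFD library in 5 of 9 SZ-A 200, 8 of 8 SZ-A 400, 9 of 9 SZ-A 600 and 1 of 7 SD libraries. Arntl lay below the lowest HFD library in 1 of 9, 4 of 8 and 9 of 9 SZ-A and in 0 of 7 SD libraries. Hspa5 lay below the lowest HFD library in 5 of 9, 5 of 8 and 9 of 9 SZ-A and in 7 of 7 SD libraries. These genes were followed after their values were seen.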
